A study of Bacillus subtilis with 19 samples.

How the data were processed

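RNA of Bacillus subtilis strains was reverse transcribed, labelled and co-hybridised in pairs to arrays of PCR products, per the labels and the series description, which gives the arrays as covering nearly all genes. The series holds 19 arrays with 2 channels each. On 4 arrays the wild-type strain AG174 (Cy3) was hybridised directly with the smc deletion strain RB35 (Cy5), in 1 dye orientation. On the other 15 arrays 1 sample (Cy3) was hybridised with a collective reference (Cy5): 3 wild-type arrays, 4 of an ftsY disruption strain (RB25), 4 of an smc disruption strain (RB27) and 4 of the smc deletion strain (RB35). The labels refer to a publication for the protocol, which was not used here. How the authors extracted, filtered and normalised the spot intensities is not given in the sources used here.

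The deposited direct-array values are log2 ratios of the 2 channels of an array. The base is not stated and was settled from the values: 21 of 127 differences between values repeated within an array equalled the log2 of a ratio of whole numbers up to 20 within 2e-06, against 0 for base e and 0 for base 10. The deposited common-reference values are given to 2 decimals and are read as log2 ratios; their base is not stated and was taken from the direct-array table. Which channel stands on top of a ratio is stated for neither table. All 105 pairs of common-reference arrays correlated positively across features, with 0.339 as the lowest Pearson r, so these arrays share 1 orientation. Values are therefore described as higher or lower deposited log2 ratios, or as the positive or negative side, and not as higher or lower expression.

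Intensities and counts were not used here, so the precision rests on the number of arrays. Direct arrays lacked a value for 701 to 1097 of 4099 features (17.1% to 26.8%). In the common-reference table no cell is empty, but on each array 1 value recurs in 86 to 2254 of 4120 features, whereas the next most repeated value of an array recurs at most 56 times. That value was treated as not measured. This was decided after the values had been seen, and the results with the repeated values kept are given as an alternative. The arrays fall into 7 with fewer than 1000 features at the repeated value (wild-type 1, ftsY disruption 1 and 3, smc disruption 2 and 3, smc deletion 1 and 2) and 8 with more. They are called nearly complete arrays and sparse arrays. These classes were drawn from the data and are not groups of the study.

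Nothing in the sources used here pairs the feature IDs of either table with genes: the gene reference matched 0 of them. Features are therefore named by their IDs, at most 2 per side of a comparison. The planned gene lists, the test of the smc and ftsY features, the test along the chromosome and the comparison of direct with common-reference effects gene by gene could not be run. Whether the features of a table are numbered in chromosomal order is not given either.

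Each array was centred on its own median. Common-reference arrays were fitted together in limma 3.58.1 (R 4.3.3) with 4 group means, and a feature was tested when it had at least 2 values in both groups of the comparison. Direct arrays were fitted with limma against 0, for features with at least 3 values. Calls are features with a Benjamini-Hochberg adjusted p under 0.05 within a comparison. These comparisons, tests and thresholds, the rule for named features and all alternatives not marked otherwise were chosen before the data were examined. The rule took, on each side, the called features with the largest fitted differences whose groups did not overlap, or whose direct arrays all lay on 1 side of 0. With fewer than 5 such features it took those with the smallest p, as not having passed. It named up to 12 features per side and was shortened to 2 per side because the features have no gene names. In tests on simulated data with 200 changed features, 30% to 53% of 2-fold changes and 77% to 88% of 4-fold changes were recovered on the common-reference arrays, and 86% and 96% on the direct arrays, with 3 to 13 false calls and 0 calls of the wrong sign. These simulated arrays varied independently and held no array class, so they do not show how many false calls the class structure gives.

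Runs of neighbouring features were sought after the values had been seen, as stretches of windows of 10 consecutive feature numbers with at least 6 measured features and a median log2 difference of at least 1 on either side of 0. Their number was compared with that in 100 shuffles of the feature order. For 5 such runs, the median deviation of an array from the feature means was compared between groups. This used 2-sided exact permutation tests of the difference of means, 30 tests in all, with Benjamini-Hochberg adjustment. Each run was chosen as a leading run of 1 comparison. Its p in that comparison, and in any comparison that shares a group with it, is not independent of the choice. The smallest p that 4 arrays against 3 or 4 against 4 gave was 0.0286, which adjusts to 0.0714 here. Correlations of the differences of 2 strains from wild-type were set beside those of 100 simulated sets of unchanged groups sharing the same 3 wild-type arrays. Figures were drawn in Python 3.11.15.

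Alternatives covered the centring, quantile normalization, the filter on missing values, the prior and moderation of limma, array weights, stricter thresholds, fits of only the 2 groups compared, the replicate block and leaving out each array in turn. Alternatives chosen after the data were seen kept the repeated values, centred on features measured on all arrays, used the array class as a block, or used 1 class alone.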

Results

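The study addressed how loss of SMC, the ATPase of the bacterial condensin complex that organises the chromosome, affects gene expression in Bacillus subtilis. Total RNA was compared on 2-colour arrays between the wild-type strain, a strain with smc deleted and a strain with smc disrupted. A strain with ftsY disrupted was included. The gene ftsY encodes the receptor of the signal recognition particle and lies next to smc on the chromosome. Whether the change at either gene altered expression of the other could not be checked, since no feature is paired with a gene. Wild-type and smc deletion RNA were hybridised directly with each other on 4 arrays, and 15 arrays set wild-type (n = 3), ftsY disruption (n = 4), smc disruption (n = 4) or smc deletion RNA (n = 4) against a collective reference. Of the 4099 features of the direct arrays, 2635 had a value on all 4 arrays and 384 on none. Of the 4120 features of the common-reference arrays, 1167 were measured on all 15 and 22 on none, and single arrays measured 1866 to 4034 of them. The number measured split the arrays within groups: 7 arrays lacked 86 to 530 features and 8 lacked 1399 to 2254, and both kinds occurred in every group, with 1 nearly complete and 2 sparse wild-type arrays.

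**Figure D1:**
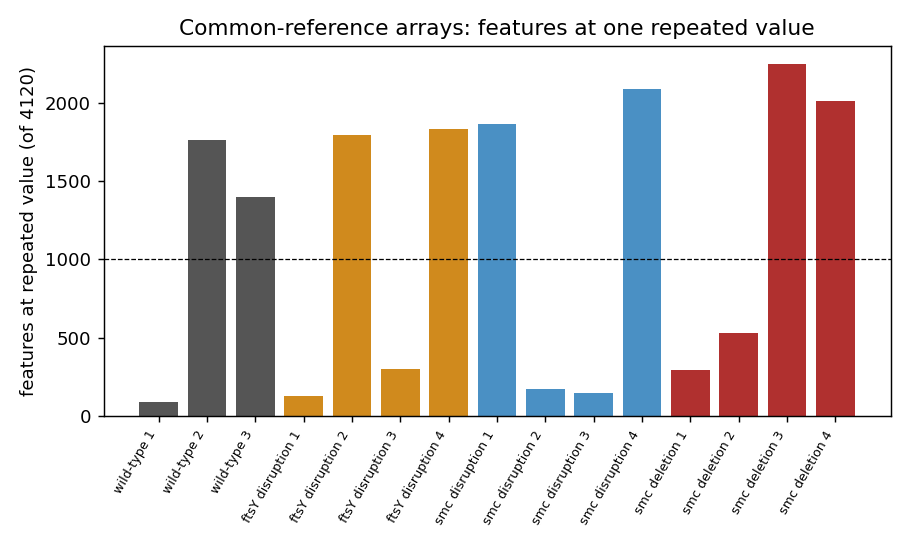
Number of features (of 4120) at the 1 repeated value of each common-reference array, read as not measured; bars are single arrays coloured by strain and the dashed line is 1000. Counts run from 86 on wild-type replicate 1 to 2254 on smc deletion replicate 3, and each strain has arrays on both sides of the line.

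Direct hybridisation of wild-type with smc deletion RNA asked which features differed between these 2 strains. Its strongest signal was a single run of neighbouring features, numbers 1210 to 1244, of which 32 were measured. The median log2 ratio of the run on an array averaged 2.55 ± 0.30 (SD, n = 4 arrays), a 5.85-fold difference between the channels. In this run 30 features were called and 29 lay beyond 2-fold on the positive side. It held 19 of the 20 largest called ratios of the array and 22 of the 29 called features beyond 4-fold. The 2 called features with the highest ratios, WGD3-1210 at 3.82 ± 0.36 (limma adjusted p = 0.000342) and WGD3-1217 at 3.63 ± 0.22 (limma adjusted p = 0.000218), belonged to it (SD, n = 4). Smaller runs on the positive side were features 1560 to 1566 (1.48 ± 0.26), 2656 to 2679 (1.18 ± 0.25) and 2944 to 2955 (1.13 ± 0.24). On the negative side were features 1107 to 1110 (-1.33 ± 0.22), 186 to 196 (-1.29 ± 0.59), 4090 to 4095 (-1.28 ± 0.48) and 3647 to 3655 (-1.10 ± 0.15). The values of all these runs are the mean ± SD of 4 array medians. Among the called features, the lowest fitted ratios were those of WGD3-3647, at -2.45 ± 1.68 (limma adjusted p = 0.0465), and WGD3-1406, at -2.10 ± 0.45 (limma adjusted p = 0.00244, SD, n = 4). The value of WGD3-3647 rested in part on 1 array at -4.96.

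In all, limma called 582 of 3103 tested features on the direct arrays (18.8%), 267 with a positive and 315 with a negative log2 ratio, and 88 positive and 71 negative calls were at least 2-fold. The 8 runs compared with at most 1 in shuffles of the feature order, and the Spearman correlation of neighbouring features was 0.39. The smc deletion RNA carried Cy5 on all 4 arrays, so an effect of the dye and an effect of the strain cannot be told apart. Replicate 3 correlated with the other 3 arrays at 0.496 to 0.515 across features, and those 3 with each other at 0.708 to 0.802. Array medians lay between 0.06 and 0.55; without centring, the median of the fitted ratios was 0.22 and the share of positive calls was 75.1% in place of 45.9%. The number of calls fell to 255 without replicate 1, 335 without replicate 2 (182 positive, 153 negative) and 247 without replicate 4. With a trend and a robust prior in limma, 300 positive and 137 negative features were called.

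**Figure D2:**
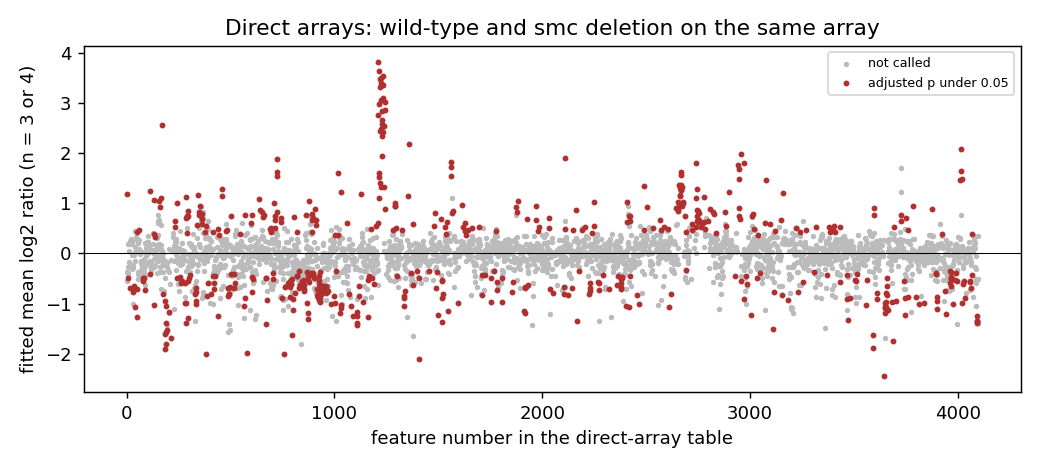
Fitted mean log2 ratio of the direct arrays (wild-type against smc deletion) by feature number; points are the 3103 tested features, red where limma called them at an adjusted p under 0.05. Features 1210 to 1244 stand above the rest on the positive side.

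Against the collective reference, smc deletion was compared with wild-type to find features that differ when smc is removed. The 7 features that limma called, of 2707 tested, all had lower log2 ratios in smc deletion. They included WGD11-3649, at 0.83 ± 1.31 in smc deletion (n = 4) and 5.15 ± 0.77 in wild-type (SD, n = 3), a log2 difference of -4.32 (limma adjusted p = 0.0212). That difference was -2.76 on sparse and -6.33 on nearly complete arrays, and its limma adjusted p was 0.0613 without wild-type 3, 0.0529 without smc deletion 1, 0.0589 without smc deletion 2 and 0.156 in a fit of these 2 strains alone. WGD11-87 was at 1.01 ± 0.81 and 4.93 ± 0.69, a difference of -3.92 (limma adjusted p = 0.00484, and 0.0821 in a fit of these 2 strains alone). The neighbours of WGD11-87, features 83 to 89, lay lower as a run, with a log2 difference of -2.62 in smc deletion (6.15-fold) and all 4 smc deletion arrays below the 3 wild-type arrays (exact permutation p = 0.0286, BH adjusted 0.0714). Features 1468 to 1484 lay higher in smc deletion, with a median deviation of 1.03 ± 0.95 against -1.20 ± 0.21 in wild-type (4.70-fold). All 4 smc deletion arrays lay above the wild-type arrays there, with an exact permutation p of 0.0571 (BH adjusted 0.107). The difference was 3.04 among sparse and 1.42 among nearly complete arrays. Features 337 to 344 were higher by 0.97, with all 4 smc deletion arrays above wild-type (exact permutation p = 0.0286, BH adjusted 0.0714). All of these runs were chosen in other comparisons with the same wild-type arrays, so their p-values here are not independent of the choice. At an unadjusted p under 0.05 there were 492 features. Array class as a block gave 158 calls (56 higher, 102 lower), among them the 7. Leaving out single arrays gave 18 (wild-type 1), 3 (wild-type 3), 4 (smc deletion 1), 4 (smc deletion 2), 53 (smc deletion 3) or 81 calls (smc deletion 4), and uncentred values 20 higher and 8 lower.

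The smc disruption strain asked the same question with another allele. Features 1468 to 1484 again lay above wild-type, by 2.15 on the log2 scale (4.45-fold), at 0.95 ± 0.98 (n = 4) against -1.20 ± 0.21 (SD, n = 3). The exact permutation p was 0.0286 (BH adjusted 0.0714). This run was chosen in this comparison, so its p here is not independent of the choice. The difference was 3.00 among sparse and 1.30 among nearly complete arrays. Features 337 to 344 were higher by 0.90 (exact permutation p = 0.0286, BH adjusted 0.0714), with all 4 smc disruption arrays above the wild-type arrays. Features 83 to 89 differed by -0.99 (exact permutation p = 0.171), with 2 of 4 arrays below wild-type. Features 337 to 344 and 83 to 89 were chosen in ftsY disruption against the same wild-type arrays. Their p-values here are not independent of the choice either. No single feature passed: limma called 0 of 2790 features, with 226 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0858. The features nearest to the threshold were WGD11-1292, with a log2 difference of -2.16 (limma adjusted p = 0.0858), and WGD11-1193, with -2.74 (limma adjusted p = 0.0872; 2 smc disruption values). On the higher side stood WGD11-344 (0.95) and WGD11-343 (1.11), both at a limma adjusted p of 0.131. With array class as a block there were 39 calls, 22 higher and 17 lower, and without wild-type replicate 1 there were 7.

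Disruption of ftsY gave more calls against wild-type, 90 of 2765 features (3.25%; limma), of which 28 were higher and 62 lower in the ftsY disruption strain. Among the 87 calls whose groups did not overlap, the largest negative differences were those of the same 2 features as in smc deletion: WGD11-3649, at 0.14 ± 0.76 (SD, n = 4), was lower by a log2 difference of -5.01 (limma adjusted p = 0.00187), and WGD11-87, at 0.89 ± 0.93 (SD, n = 4), by -4.04 (limma adjusted p = 0.000788). The largest positive differences among them were those of WGD11-155, at 2.03 (limma adjusted p = 0.00906), and WGD11-343, at 1.79 (limma adjusted p = 0.000788). WGD11-343 sits in features 337 to 344, which as a run were higher by 1.42 (2.67-fold; exact permutation p = 0.0286, BH adjusted 0.0714). That run thus lay above the same 3 wild-type arrays in all 3 strains. Features 328 to 334, a few numbers away, were lower by a log2 difference of -3.16 (8.92-fold) and features 83 to 89 by one of -2.74 (6.69-fold). In each, all 4 arrays lay below wild-type (exact permutation p = 0.0286, BH adjusted 0.0714). Features 337 to 344, 328 to 334 and 83 to 89 were chosen in this comparison, so their p-values here are not independent of the choice. Features 1468 to 1484, in contrast to both smc strains, lay at -1.20 ± 0.86 against -1.20 ± 0.21 in wild-type (exact permutation p = 1). The difference was 0.65 among sparse and -0.65 among nearly complete arrays. In all 83 calls were at least 2-fold and 571 features had an unadjusted p under 0.05. Array class as a block gave 222 calls, with 89 of the 90 among them. Leaving out single arrays gave 29 (wild-type 3), 16 (ftsY disruption 1), 37 (ftsY disruption 2) or 20 calls (ftsY disruption 3). Without wild-type replicate 1 there were 35 higher and 29 lower calls, and with quantile normalization 21 higher and 24 lower.

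**Figure D3:**
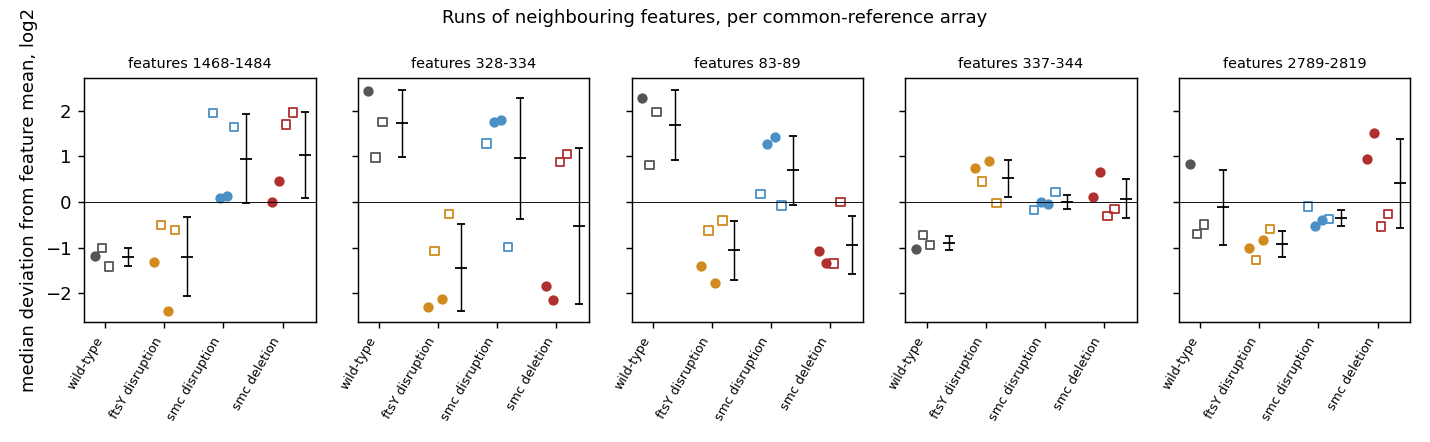
Median deviation of each common-reference array from the feature means (log2) in 5 runs of neighbouring features; filled circles are nearly complete arrays, open squares sparse arrays, bars the mean ± SD of a group. In features 1468 to 1484 the 8 smc arrays lie at or above 0.004 and the 7 other arrays at or below -0.51.

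Contrasts between the disrupted strains asked which features separate the smc strains from the ftsY disruption strain. The run of features 1468 to 1484 did so in both alleles: smc deletion lay above ftsY disruption by 2.23 and smc disruption by 2.15 on the log2 scale (exact permutation p = 0.0286 each, BH adjusted 0.0714), and the 2 smc strains differed by 0.08 (exact permutation p = 0.857). The run was chosen in smc disruption against wild-type, so only the p of smc deletion against ftsY disruption is independent of the choice. All 8 smc arrays lay above all 7 wild-type and ftsY disruption arrays. Features 3068 to 3086 also lay above ftsY disruption, with a median log2 difference of 1.36 in smc deletion and 1.35 in smc disruption. Above wild-type they lay by 1.18 in smc deletion (exact permutation p = 0.0571, BH adjusted 0.146) and by 1.15 in smc disruption (exact permutation p = 0.0286, BH adjusted 0.131). Both were adjusted over 46 tests of runs. Against ftsY disruption, limma called 17 of 3523 features in smc deletion, 15 higher and 2 lower, and 26 of 3754 in smc disruption, 17 higher and 9 lower. Among these calls the largest positive differences of smc deletion were those of WGD11-2808 (3.19; limma adjusted p = 0.0188; 3 against 2 values) and WGD11-2801 (2.51; limma adjusted p = 0.0442; 3 against 2 values), both in features 2789 to 2819. That run was higher than in ftsY disruption by 1.33 in smc deletion and by 0.58 in smc disruption (exact permutation p = 0.0286 each, BH adjusted 0.0714). The run was chosen in smc deletion against ftsY disruption, and both contrasts hold the ftsY disruption arrays. Neither p is therefore independent of the choice. On sparse arrays only 1 to 16 of its 31 features were measured. The 2 lower calls were WGD11-4048 (-1.30) and WGD11-1000 (-1.10), both at a limma adjusted p of 0.0461; 1 of the 4 ftsY disruption arrays stood apart for WGD11-1000.

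Among the calls for smc disruption against ftsY disruption, the largest positive differences were those of WGD11-123 (4.05; limma adjusted p = 0.0340; 2 against 3 values) and WGD11-3649 (3.18; limma adjusted p = 0.0457). The largest negative ones among these calls were those of WGD11-408 (-1.58) and WGD11-3797 (-1.37), both at a limma adjusted p of 0.0457. Features 83 to 89 were higher than in ftsY disruption by 1.75 (3.37-fold, exact permutation p = 0.0286, BH adjusted 0.0714), with 4 of 4 arrays above. The difference was 0.56 among sparse and 2.94 among nearly complete arrays. This run was chosen in ftsY disruption against wild-type, so its p here is not independent of the choice. Between the 2 smc strains limma called 0 of 3589 features, with 383 at an unadjusted p under 0.05. The smallest adjusted p was 0.0520, for WGD11-3739 (2.50) and WGD11-3325 (2.39), each with 2 values per group. On the lower side stood WGD11-87 (-2.65; limma adjusted p = 0.0542) and WGD11-88 (-2.32; limma adjusted p = 0.0626). In smc deletion 1 array stood apart for both. Without a single array the count for smc deletion against ftsY disruption was 0 (ftsY disruption 1 or 3, smc deletion 1), 6 (ftsY disruption 2, smc deletion 3), 8 (smc deletion 2; 2 higher and 6 lower) or 36 (smc deletion 4). For smc disruption it was 1 (ftsY disruption 1 or 3), 0 (ftsY disruption 2, smc disruption 2 or 3), 8 (smc disruption 1) or 87 (smc disruption 4). With repeated values kept these counts were 0 for smc deletion and 1 for smc disruption, and with array class as a block 91 and 161. Between the smc strains 4 features were called without smc disruption 1, 23 without smc deletion 4, 32 with array class as a block and 22 with quantile normalization.

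Across 2686 features, the differences of smc deletion and of ftsY disruption from wild-type had a Pearson correlation of 0.760, against 0.548 in simulations of unchanged groups that share the 3 wild-type arrays. The 7 features called lower in smc deletion were all among the 62 called lower in ftsY disruption; both sets of calls rest on the same 3 wild-type arrays, and the overlap was not tested. The 2 smc strains correlated at 0.685 against 0.543 simulated, and smc disruption and ftsY disruption at 0.417 against 0.549. The covariance lay above the simulated one in all 3 pairs: 0.341 against 0.0879, 0.215 against 0.0892 and 0.134 against 0.0886, in the same order. Features are not independent replicates, so these values carry no p. The simulated arrays varied independently and held no array class. Deviations of real arrays of different strains correlated at 0.147 on average within a class and -0.150 between classes. A departure from the simulations therefore cannot be told apart from this class structure. Neighbouring features changed alike in each comparison: Spearman correlations of neighbours ran from 0.24 to 0.39, with at most 0.052 after shuffling. Runs numbered 12 in smc deletion, 4 in smc disruption and 18 in ftsY disruption against wild-type, and at most 5, 1 and 6 after shuffling. The runs described here were found on the same arrays. In 46 tests, a run was compared between 2 groups whose arrays had not been used to find it. Of these, 10 had an exact permutation p under 0.05 and 0 an adjusted one, with 0.131 as the smallest BH adjusted p. Stretches such as features 83 to 89 recur among the 46, so the tests are not independent.

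Arrays of 1 strain did not all resemble each other. Array pairs of the same strain and class correlated at 0.837 on average and pairs of the same strain but different class at 0.625. In smc deletion, replicates 1 and 2 correlated with replicates 3 and 4 at 0.548 on average. Replicates 3 and 4 of smc deletion correlated with smc disruption replicates 1 and 4 at 0.869. Replicates 1 and 2 of smc deletion stood nearer to ftsY disruption replicates 1 and 3 (0.609) than to smc disruption replicates 2 and 3 (0.528). The ftsY disruption arrays divided in a like way, with replicates 1 and 3 correlating with replicates 2 and 4 at 0.499 to 0.563. On the first 3 principal components of the 1167 features measured on all 15 arrays fell 38.3%, 18.5% and 12.5% of the variance. Array medians of measured features lay between -0.45 and 0.02. Without centring, the median difference from wild-type was 0.14 in smc deletion, 0.17 in smc disruption and -0.005 in ftsY disruption. It was 0.03 between the smc strains, and 0.22 for smc deletion and 0.21 for smc disruption against ftsY disruption. The share of higher calls against ftsY disruption moved with it, from 88.2% to 95.7% in smc deletion and from 65.4% to 90.9% in smc disruption, and to 71.7% and 50.4% under quantile normalization. All changes above are relative to the median of each array.

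**Figure D4:**
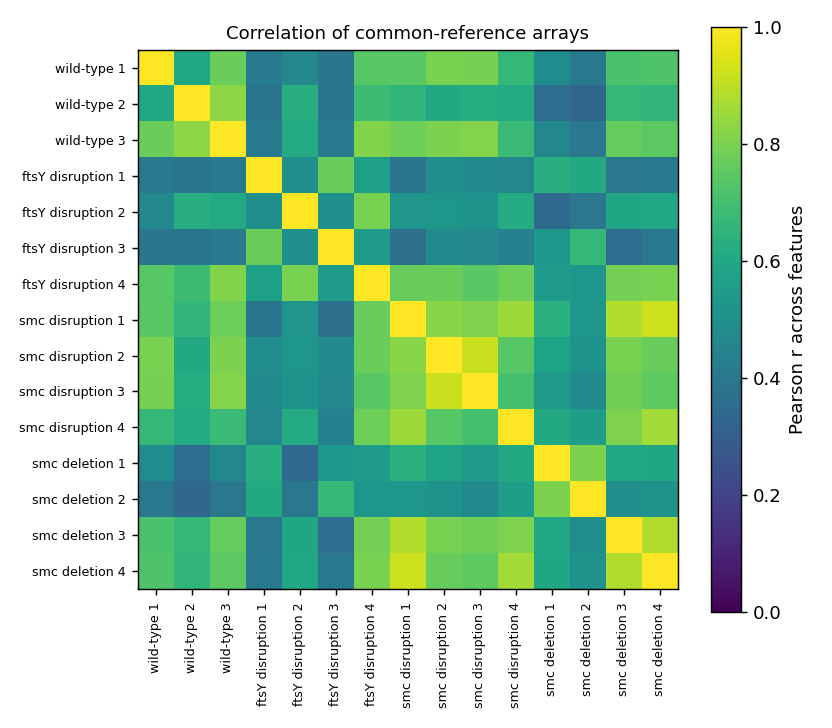
Pearson correlation across features of each pair of the 15 common-reference arrays, on median-centred log2 ratios; the diagonal is 1. smc deletion replicates 1 and 2 correlate less with the other smc arrays than smc deletion replicates 3 and 4 do, and the lowest of the 105 pairs is 0.339.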

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

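The tests of explanations, the counts over other splits of the arrays, the search for runs and the array classes were chosen after the results had been seen; the search for single arrays that stand apart was fixed earlier.

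Features 1468 to 1484 lay higher in both smc strains than in wild-type and in ftsY disruption; features 3068 to 3086 showed a smaller difference of the same kind and were not weighed. The smallest of the 4 within-class differences from wild-type was 1.30 on the log2 scale, against an SD of 0.348 between single arrays of a strain and class. That value rests on arrays used to find the run and on 1 nearly complete wild-type array, so it cannot decide about array class. On the same run, found without either group, smc deletion lay above ftsY disruption by 2.38 among sparse and 2.07 among nearly complete arrays. These values argue against array class as the cause of that contrast. Chance values of the 3 wild-type arrays are argued against by smc deletion against ftsY disruption, 2.23 on a run found without either group (exact permutation p = 0.0286, 4 of 4 arrays above). Loss of smc predicts the same for the other allele, and on the run found in smc deletion against wild-type, smc disruption lay above ftsY disruption by 1.95 (exact permutation p = 0.0286, 4 of 4 arrays above). Each p is the smallest possible, and neither passes adjustment over the 46 tests of runs (BH adjusted 0.131). Features 1461 to 1495, found without the arrays tested, lay above wild-type by 1.92 in smc disruption and 1.98 in smc deletion (exact permutation p = 0.0571 each, BH adjusted 0.146). A change that follows loss of smc therefore stays a hypothesis. So does an unlabelled difference that the arrays of both smc strains might share, which was not tested.

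The smc deletion arrays divide into replicates 1 and 2 and replicates 3 and 4. A single effect of the array class, common to all strains, is argued against by low correlations of the nearly complete minus sparse difference. That of smc deletion correlated with that of smc disruption at 0.106 and with that of wild-type at -0.00136. Against that, those of wild-type and smc disruption correlated at 0.367. The wild-type difference rests on 1 nearly complete array, and a weaker class effect shared by the strains stays open. That replicates 1 and 2 are wild-type or ftsY disruption samples is argued against by features 1468 to 1484. There they were at 0.004 and 0.45 and the 7 arrays of those strains at -0.51 or below. Whether replicates 1 and 2 are smc disruption samples cannot be decided from correlations. The highest of any smc disruption array with either was 0.638, against 0.801 between those 2. With smc deletion replicates 3 and 4 they correlated at 0.595 or below, so the same measure would reject their own label too. Whether smc deletion replicates 3 and 4 are smc disruption samples was not tested and stays open. They correlated with smc disruption replicates 1 and 4 at 0.869 on average, against 0.837 for pairs of the same strain and class. The nearly complete minus sparse difference of smc deletion appeared in ftsY disruption too, with a correlation of 0.667. A condition that the labels do not give, such as growth or a separate set of hybridisations, may be shared by these 2 strains; it cannot be told apart from samples of another origin, since the labels name no batch, day or medium.

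Features 83 to 89 lay lower than wild-type in ftsY disruption and smc deletion. Array class as the cause is argued against by the smallest of the 4 within-class differences, -1.90, against an SD of 0.498 between single arrays of a strain and class. That is the log2 difference of ftsY disruption on sparse arrays. Features 83 to 89 were also found as a run between the 2 smc strains, without ftsY disruption or wild-type arrays. The differences on nearly complete arrays rest on 1 wild-type array. For ftsY disruption, chance values of the wild-type arrays were weighed on a run found without smc disruption or ftsY disruption arrays. There smc disruption lay above ftsY disruption by 1.46 (exact permutation p = 0.0286, BH adjusted 0.131, 4 of 4 arrays above). On features 83 to 89 the difference of these strains was 0.56 among sparse and 2.94 among nearly complete arrays. For smc deletion the matching test against smc disruption gave -1.63 (exact permutation p = 0.0571, BH adjusted 0.146). On the run found between smc disruption and ftsY disruption, smc deletion differed from wild-type by -2.62 (exact permutation p = 0.0286, BH adjusted 0.131). None of these tests passes adjustment, which leaves chance values of the wild-type arrays open for both strains. Both parts of the divided smc deletion arrays lay below wild-type, by log2 differences of -3.48 on nearly complete and -2.06 on sparse arrays, and a biological difference of the strains stays among the open explanations.

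Other splits of the same arrays into groups of equal sizes, 35 for each comparison, give a measure of chance for the counts of calls. For ftsY disruption against wild-type, 1 of 35 splits gave as many calls, the real one (90 calls; highest other 5), and for smc disruption against ftsY disruption also 1 (26 calls; highest other 0). Each is the smallest share that 35 splits can give, which argues against chance for that comparison taken alone. With no adjustment over the 6 comparisons, chance is not excluded. The 26 calls fell to 0 without ftsY disruption 2, smc disruption 2 or smc disruption 3, and to 1 without ftsY disruption 1 or 3. For smc deletion against wild-type, 2 of 35 splits gave as many (7 calls; highest other 28, with smc deletion replicate 4 placed among the wild-type arrays), and chance is not excluded. For smc deletion against ftsY disruption, 3 of 35 gave as many (17 calls; highest other 292, several times the real count), where the largest split followed the array class and points to that structure; array class as a block gave 91 calls. For smc disruption against wild-type and for the 2 smc strains, limma called 0 features (226 and 383 at an unadjusted p under 0.05), so all 35 splits gave as many; the highest others, 89 and 24, followed the array class, and the class as a block gave 39 and 32 calls.

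A single array stood far from the others of its group in 5 of 58 groups of values tested (named features, runs, array medians and numbers of missing values), where chance gives about 1 in 20. For WGD11-87 in smc deletion 1 array was at 2.23 and the others at 0.56 to 0.65. For WGD11-88 in smc deletion 1 array was at 2.56 and the others at 0.37 to 0.56. For WGD11-344 in smc disruption 1 array was at -0.04 and the others at -0.60 to -0.54. For WGD11-1000 in ftsY disruption 1 array was at -0.29 and the others at 0.26 to 0.30. For WGD3-3647 on the direct arrays 1 array was at -4.96 and the others at -1.82 to -1.51.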

How the results depend on the processing

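Alternatives that kept the repeated values, centred on features measured on all arrays, or used the array class, and all alternatives for runs and correlations, were chosen after the data were seen; the others follow the plan. Counts are given in the order smc deletion, smc disruption and ftsY disruption against wild-type, then smc deletion against smc disruption, smc deletion against ftsY disruption and smc disruption against ftsY disruption; they were 7, 0, 90, 0, 17 and 26, with 582 on the direct arrays. Of 488 values of named features under alternatives 0 changed sign; 357 kept their side of the threshold, 90 lost the call and 41 gained one. WGD3-1210 and WGD3-1217 kept theirs in 11 of 11 alternatives and WGD3-3647 lost it in 6 of 11. In smc deletion against wild-type WGD11-87 lost its call in 2 and WGD11-3649 in 6 of 21. In ftsY disruption WGD11-87, WGD11-3649 and WGD11-343 kept theirs in 21 of 21, and WGD11-155 lost it in 1 of 21. In smc deletion against ftsY disruption the call was lost in 4 (WGD11-2808) and 7 of 18 (WGD11-2801), 10 of 21 (WGD11-4048) and 13 of 22 (WGD11-1000). In smc disruption against ftsY disruption it was lost in 6 of 18 (WGD11-123), 10 of 22 (WGD11-3649), 12 of 21 (WGD11-408) and 12 of 22 (WGD11-3797).

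Counts within 1.5 times those above are given here beside those that moved further. Uncentred values gave 28, 0, 78, 0, 46 and 33 (direct 526), quantile normalization 17, 0, 45, 22, 92 and 123 (direct 603). Features measured on every array gave 28, 1, 71, 0, 0 and 36 (direct 577), and no filter 36, 0, 48, 0, 15 and 26 (direct 539). The trend and robust prior gave 5, 1, 76, 0, 32 and 67 (direct 437), array weights 194, 131, 289, 67, 52 and 380 (direct 670). Unmoderated statistics gave 0, 0, 13, 0, 0 and 1 (direct 130). The stricter adjusted p of 0.01 gave 3, 0, 14, 0, 0 and 0 (direct 197) and a 2-fold minimum 7, 0, 83, 0, 17 and 25 (direct 159), both by construction. Fits of only the 2 groups gave 1, 1, 45, 9, 1 and 233, and the replicate block 4, 0, 46, 0, 0 and 2. The replicate numbers did not pair the arrays of different groups: 4 of 15 arrays correlated best with an array of another group carrying their own number, and 7 of 21 pairs of equal number correlated above 0.1 in their deviations. Repeated values kept gave 14, 2, 54, 0, 0 and 1, and centring on common features 17, 0, 92, 0, 40 and 21. Array class as a block gave 158, 39, 222, 32, 91 and 161. Sparse arrays alone gave 47, 61, 106, 1, 27 and 52, and nearly complete arrays alone 537, 138, 590, 390, 126 and 488; the latter hold 1 wild-type array, which is assumed to vary like the other groups. Unadjusted counts by limma were 492, 226, 571, 383, 448 and 714 (direct 1069). Apart from the stricter threshold and the 2-fold minimum, the cause was not tested.

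Without single arrays the counts ran from 3 to 81 for smc deletion against wild-type (18 without wild-type 1, 3 without wild-type 3, 4 without smc deletion 1 or 2, 53 without smc deletion 3, 81 without smc deletion 4). They ran from 0 to 7 for smc disruption (7 without wild-type 1) and from 16 to 130 for ftsY disruption (29 without wild-type 3, 16, 37 and 20 without ftsY disruption 1, 2 and 3, 130 without wild-type 2). They ran from 0 to 23 between the smc strains (4 without smc disruption 1, 23 without smc deletion 4). For smc deletion against ftsY disruption they ran from 0 to 36 (0, 6 and 0 without ftsY disruption 1, 2 and 3; 0, 8, 6 and 36 without smc deletion 1, 2, 3 and 4), and for smc disruption from 0 to 87 (1, 0 and 1 without ftsY disruption 1, 2 and 3; 8, 0, 0 and 87 without smc disruption 1, 2, 3 and 4). On the direct arrays they ran from 247 to 675 (255, 335 and 247 without replicates 1, 2 and 4, and 675 without replicate 3). The cause was not tested. The share of higher calls moved with the scaling: from 0% to 71.4% uncentred and 52.9% with quantile normalization for smc deletion against wild-type, and from 31.1% to 37.2% and 46.7% for ftsY disruption. On the direct arrays it moved from 45.9% to 75.1% and 45.1%. Other settings turned the majority side of the calls too: centring on common features (9 higher, 8 lower) and sparse arrays alone (25 and 22) for smc deletion against wild-type, leaving out wild-type 1 (35 and 29) for ftsY disruption, leaving out smc deletion 2 (2 and 6) for smc deletion against ftsY disruption, and repeated values kept (0 and 1) for smc disruption against ftsY disruption. On the direct arrays the trend and robust prior (300 and 137), the 2-fold minimum (88 and 71) and leaving out replicate 2 (182 and 153) did so.

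Of 165 values of runs 150 kept their direction and, where tested, their side of an exact p of 0.05, 6 lost and 3 gained such a p and 6 changed sign; values without single arrays carry no test. Features 1468 to 1484 in ftsY disruption against wild-type, at 0.006, were at -0.0031 uncentred, -0.10 centred on common features, -0.08 without wild-type replicate 3, -0.22 without ftsY disruption replicate 2 and -0.18 without ftsY disruption replicate 4, and ran from -0.22 to 0.37 without single arrays. Features 2789 to 2819 in smc disruption against wild-type, at -0.23, were at 0.25 without wild-type replicate 1 and ran from -0.51 to 0.25 without single arrays. The cause was not tested. The correlation of the differences of smc deletion and ftsY disruption was 0.678 with quantile normalization and 0.809 on features measured on every array, and 0.710 to 0.817 without single arrays. That of smc disruption and ftsY disruption was 0.333, 0.503 and, with array class as a block, 0.507, and 0.312 to 0.572 without single arrays. That of the 2 smc strains was 0.597 to 0.778 without single arrays. The cause was not tested.

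Not run, because nothing pairs the features with genes, were the alternatives for gene lists, chromosome position and the smc locus, and those for the comparison of direct with common-reference effects. Signal over background is not given in the sources used here, so its effect on the limit of detection is unknown.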

Other observations

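Both tests described in this part were chosen after the results had been seen.

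Beyond the runs described for each strain, features 2789 to 2819 had a median deviation of 0.41 ± 0.97 in smc deletion, -0.35 ± 0.18 in smc disruption, -0.92 ± 0.29 in ftsY disruption (SD, n = 4 each) and -0.12 ± 0.82 in wild-type (SD, n = 3). Against wild-type the log2 difference of ftsY disruption was -0.80 (exact permutation p = 0.0571, 3 of 4 arrays below), and the 2 sparse wild-type arrays measured 2 and 3 of these 31 features. Features 328 to 334 differed within smc deletion, where the log2 difference from wild-type was -4.42 on nearly complete arrays and -0.41 on sparse arrays; over all 4 arrays the difference was -2.24 (exact permutation p = 0.143).

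A hypothesis links the run of features 1210 to 1244 of the direct arrays with the run around features 1468 to 1484 of the common-reference arrays: they may be the same features under 2 numberings. If so, the profile of ratios along the direct run should match best at that position of the other table. When it was slid along 4086 positions of the differences of smc disruption from ftsY disruption, the position at features 1462 to 1496 had rank 1, with a Spearman correlation of 0.735 and 0.582 at the best position that does not overlap it. It was also first for smc deletion against ftsY disruption (0.766, next 0.702) and for smc disruption against wild-type (0.688, next 0.635), and second for smc deletion against wild-type (0.692, with 0.709 at features 3362 to 3396). The 4 scans share arrays and the run was already known to stand out, so they are not independent. If the hypothesis holds, the ratios of the 2 tables have different channels on top, since the smc strains carried Cy5 on the direct arrays and Cy3 on the others. No single shift of the numbering by up to 400 brought the 2 tables together, with correlations of at most 0.107 for missing values and 0.079 for fold changes, and no comparison feature by feature was made.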
